A study of Arabidopsis thaliana with 3 samples.

How the data were processed

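RNA from leaves of Arabidopsis thaliana was measured on 3 Affymetrix Arabidopsis genome arrays, an early short-oligonucleotide array that reports 1 value per probe set, a group of short probes designed against 1 transcript. Per the labels, 2 arrays held RNA pooled from leaves of several T2 plants of 35S:WIN1 line 13 and of 35S:WIN1 line 22, and 1 array held RNA pooled from leaves of several plants carrying an empty binary vector. Per the labels, labelled cRNA was prepared, hybridised and scanned by the manufacturer's procedure. Per the file headers, the 3 arrays were of 1 chip lot and were scanned in 1 session, so there was no lot or session to test as a batch. The software and the method that summarised the probes of a probe set are not given in the sources used here.

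The deposited values were linear intensities, 1 for each of 8247 probe sets, with between 13.6% and 16% of the values of an array at or below 0. The deposited intensity of the arrays had medians of 70.2 in line 13, 35.2 in line 22 and 84.1 in the control, so the authors' values had not been brought to a common level. Negative values point to a subtracted background, but no header or label records that step.

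The choices of this paragraph and the next were made before the data were examined. Each array was multiplied by 1 factor (0.981 for line 13, 1.40 for line 22 and 0.788 for the control) that brought its mean, trimmed by 2% at each end, to a common 176.6. Values below 0 were set to 0, a pseudocount of 18.6 was added (the 20th percentile of the positive scaled values), and log2 was taken. All log2 ratios are therefore on the log2(value + pseudocount) scale, which understates the ratio of dim probe sets, and no ratio is a fold against a value at or below 0. Probe sets whose mean log2 value over the 3 arrays lay above the 30th percentile were kept, which left 5773 and set aside 2474 as dim.

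The lines were compared with the control by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes, a trend of the spread with intensity, and Benjamini-Hochberg adjustment over the kept probe sets. With 2 lines and 1 control the fit has 1 residual degree of freedom, which comes from the spread between the lines, and the lone control was assumed to vary like the lines. eBayes pooled the spread between the lines over all kept probe sets, with a median of 85.3 prior degrees of freedom against 1 residual. The p-values therefore rest mostly on that pooled spread and little on a probe set's own difference between the lines. The small number of arrays limits the precision of every value. Beside this test, probe sets were counted by a rule of size with no test: a log2 ratio to the control of at least 1 in both lines, with the same sign. The named genes were fixed by a rule: among kept probe sets paired with 1 gene, the 12 highest and the 12 lowest that met the rule of size, ranked by the smaller of the ratios of the lines; up to 10 past adjusted p; the measured members of the wax list and the cutin and suberin list; up to 4 members of each other list by size of the mean ratio; and the 5 with the largest difference between the lines in each direction. The WIN1 gene was to be reported where measured.

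Both ratios share the control array, so their agreement was set beside 100 simulations of unchanged lines. Noise of line 13 and of the control was drawn from the line 13 ratios within intensity deciles, and noise of line 22 from the line 22 ratios, with the control as noisy as line 13. This gives the control 50% of the variance of the line 13 ratios, an assumption that 1 control array cannot check. Sets of 100 simulations with shares of 60%, 70%, 80%, 90% and 100% were added after the data had been seen.

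Gene names came from a table that pairs probe sets with GEO's platform annotation, updated by gene ID through a RefSeq gene table of assembly TAIR10.1. Of the 8247 probe sets, 3794 were paired with 1 gene, 70 with several and 4383 with none, and a probe set without a pair is unnamed here, not without a gene. Of the 3794, 3784 matched a locus, which made 3592 loci, and 10 gene IDs had no match. No coordinates are printed because the files name no genome build. The 18 gene lists had 332 members given by locus, of which 24 matched a probe set and 19 were kept. Probe sets of 1 gene were averaged before the lists were tested with camera, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, for the 2 lists with at least 3 measured genes. With 1 residual degree of freedom, the estimated correlation rests on the difference between the lines alone, so it is a weak check wherever it is given. The percentile of a list mean was taken among 10000 random lists matched on intensity.

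The procedure was tested on simulated data with 200 changed probe sets among the 5773. Of 100 probe sets changed 4-fold, limma recovered 0 and the rule of size 85. Of 100 changed 16-fold, limma recovered 48 and the rule of size 100. Among the unchanged probe sets limma called 2 and the rule of size 48. Of 2 simulated lists of 20 genes, the shifted one had a camera p of 7.23e-14 and the unshifted one 0.645.

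Alternatives tried were the deposited values without scaling, scaling to a common median, quantile normalization, pseudocounts at the 5th and 40th percentiles, a floor in place of the pseudocount, no filter, a filter at the 50th percentile, fold thresholds of 1.5 and 3, eBayes without the trend, robust eBayes, and each line alone. Families of genes tested in the closing section were put together after the data had been seen, by shared symbol or from general knowledge of the loci, and 1 of them is not reported here. Intervals over probe sets of the same gene came from 1000 bootstrap samples of genes. Plots were drawn with matplotlib 3.10.9. The scanner records of the arrays hold no value per probe set and were not used.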

Results

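Leaf transcripts of Arabidopsis thaliana plants that overexpress WIN1 were compared with those of plants carrying an empty vector. WIN1 is an AP2/ERF transcription factor whose overexpression is known to make leaves glossy by increasing their epidermal wax, and the 35S promoter of cauliflower mosaic virus drives it in most tissues. The WIN1 group had 2 arrays, from the independent transgenic lines 13 and 22, and the control group had 1. Each array held pooled leaf RNA, so there was 1 measurement per line, errors are the SD between the 2 lines, and the control had no replicate. Both ratios use that 1 control array, so the SD between the lines leaves out its error. The arrays gave linear intensities for 8247 probe sets, of which 5773 were bright enough to be kept. The median deposited intensity was 70.2 in line 13, 35.2 in line 22 and 84.1 in the control, and the arrays were scaled to a common trimmed mean before any ratio was taken. No probe set in the tables used here was paired with the WIN1 locus AT1G15360, so the level of the overexpressed gene itself was not analysed here.

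The first comparison asked which transcripts differed between WIN1 overexpressors and the control. Two-sided limma tests adjusted by the Benjamini-Hochberg method found 2 probe sets past an adjusted p of 0.05, both higher in both lines and neither paired with a gene. They fall outside the rule for named genes and were singled out after their values had been seen. Probe set 12513_at had a scaled intensity of 3484 in line 13 and 2366 in line 22 against 11.5 in the control. Its log2 ratio was 6.59 (limma SE 0.73, n = 2 lines; limma adjusted p = 2.49e-10). Probe set 18955_at had scaled intensities of 78.7 and 411.3 in lines 13 and 22, and its control value of -0.5 lay below 0. Its log2 ratio on the pseudocount scale was 3.46 (limma SE 0.759, n = 2 lines; limma adjusted p = 0.0492). Without adjustment, limma gave 129 probe sets a p under 0.05, fewer than the 288.7 that chance gives for 5773 tests if the error is estimated rightly. The limma error came from the spread between the lines (SD 0.898 over kept probe sets). That spread was wider than that of the line 13 ratios to the control (SD 0.401). The low count may therefore reflect an overstated error and is no evidence that few transcripts changed. The call for 12513_at ended under quantile normalization (limma adjusted p = 0.161), with a floor in place of the pseudocount (0.278) and without the filter on dim probe sets (0.227), with log2 ratios of 6.57, 7.27 and 6.59. That for 18955_at ended under each alternative scaling, pseudocount or floor and without the filter (0.191 to 1, with log2 ratios from 2.15 to 5.54), without the trend (0.0616) and with robust eBayes (0.166).

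The 12 named genes with the highest ratios in both lines included GPDHC1 and AT1G05310. GPDHC1 (AT2G41540), a cytosolic NAD-dependent glycerol-3-phosphate dehydrogenase, had scaled intensities of 562.5 in line 13 and 612.4 in line 22 against 75.6 in the control, a mean log2 ratio of 2.69 ± 0.084 (SD, n = 2). The limma SE of the GPDHC1 ratio was larger, 0.739, since the SD leaves out the error of the control. AT1G05310, a member of the pectinesterase family, had 608.9 and 948 against 99.6, a mean log2 ratio of 2.72 ± 0.441. The GDSL-type lipase genes AT2G04570 and AT2G42990 had mean log2 ratios of 2.68 ± 0.954 and 2.13 ± 0.201, and AT2G39980, of the HXXXD-type acyltransferase family, had 1.85 ± 0.258. AT2G04570 had a scaled intensity of 1521 in line 13 and 585.6 in line 22 against 132.3 in the control. The other 7 were AT4G15140, AT1G03010, AT4G24130, AT2G23440, AT2G34930, AT1G24230 and AT2G20870, with mean log2 ratios from 1.32 for AT2G20870 to 2.16 for AT4G24130. The control value of AT2G23440 was -5, below 0, and those of AT2G42990 (13.7), AT4G24130 (13.8), AT4G15140 (8), AT1G03010 (6.2) and AT1G24230 (9.9) lay under the pseudocount of 18.6, which therefore sets the size and order of these 6 ratios. The ratio of AT2G42990 was 2.84 and 1.35 with pseudocounts at the 5th and 40th percentiles. None of the 12 passed the limma test, in which the lowest adjusted p was 0.371, shared by GPDHC1, AT1G05310 and AT2G04570. All 12 were higher in both lines under each alternative scaling, and on the deposited values without scaling 9 of them still met the 2-fold rule in both lines. With a pseudocount at the 40th percentile 6 of them met it.

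The named gene with the lowest ratios in both lines was AT4G29020, which encodes a glycine-rich protein. Its scaled intensity was 116.4 in line 13 and 87.4 in line 22 against 1012 in the control, a mean log2 ratio of -3.11 ± 0.247 (SD, n = 2; limma adjusted p = 0.0831), and it passed the limma test only with a pseudocount at the 40th percentile (adjusted p = 0.0394). AT3G47800 had scaled intensities of 414.8 and 184.1 against 1080, a mean log2 ratio of -1.89 ± 0.775. CHI (AT2G43570), listed as a putative chitinase, had 215.8 and 117.6 against 548.1, a mean log2 ratio of -1.67 ± 0.554. MSRB6, a methionine sulfoxide reductase, had 45.9 in line 13 and a value below 0 in line 22, against 132.8 in the control. AT3G47380, of the pectin methylesterase inhibitor family, was read by a pair of probe sets that gave similar log2 ratios, -0.82 and -1.05 in line 13 and -1.96 and -1.95 in line 22. The remaining 7 were AT2G44330, AT4G01410, AT3G09010, AT4G30940, AT4G24480, AT2G36970 and AT2G01460, with mean log2 ratios from -2.13 for AT3G09010 to -1.29 for AT2G36970. In line 22 the values of AT2G44330, AT3G09010, MSRB6 and AT2G01460 were below 0, so that no level above background was measured there. Those of AT4G30940 (5.5), AT3G47380 (9.2), AT4G01410 (12.1) and AT4G24480 (13.2) lay under the pseudocount. In line 13 the values of AT2G44330 (9), AT4G24480 (10.7) and AT4G30940 (11.7) also lay under it. These low values limit how far the ratios of these genes measure a size. None of the 12 passed the limma test, and all 12 were lower in both lines under each alternative scaling. With a pseudocount at the 40th percentile 6 of them were at least 2-fold lower in both lines.

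**Figure D1:**
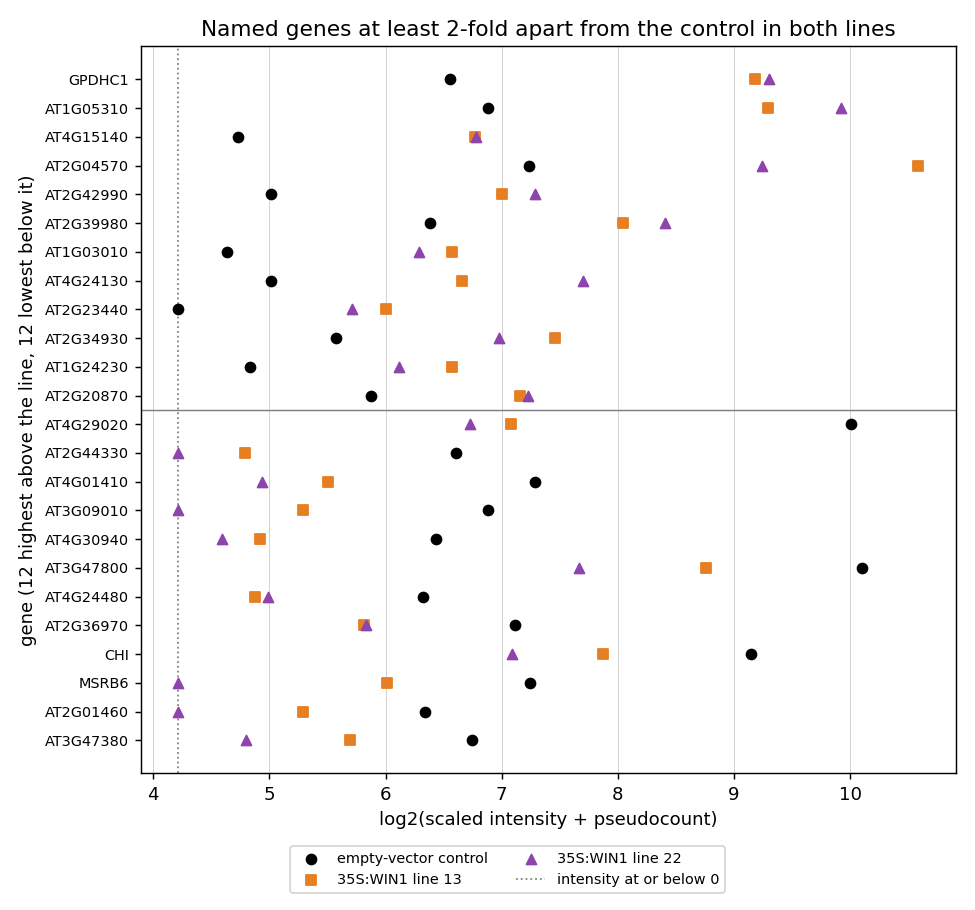
Scaled intensity on the log2(value + pseudocount) scale (x axis) of the 12 highest and the 12 lowest named genes (y axis) in the control (circles), line 13 (squares) and line 22 (triangles), 1 array each. The dotted line marks values at or below 0, where the control value of AT2G23440 lies, and AT4G29020 lies at 1012 scaled units in the control against 116.4 and 87.4 in the lines.

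By the rule of size alone, 82 kept probe sets differed from the control at least 2-fold the same way in both lines, 50 higher and 32 lower, and 17 and 14 of these were paired with 1 gene. The share that was higher was 61%, but it was 17.1% on the deposited values without scaling (22 higher and 107 lower), where the median log2 ratio over kept probe sets was -0.27 in line 13 and -0.78 in line 22. Line 13 alone had 158 such probe sets (86 higher and 72 lower), and line 22 alone had 1372 (426 higher and 946 lower). Independent lists of those sizes would share 6.3 higher and 11.8 lower probe sets. Simulated unchanged lines against a shared control gave 37 to 74 probe sets in 100 simulations (mean 56.3) with a control as noisy as line 13. The noise of the lone control is not known, and simulations added after the data had been seen gave a mean of 66.5 (47 to 83) when the control held 60% of the variance of the line 13 ratios and 107.5 (82 to 127) when it held 100%. Across kept probe sets, which are not independent replicates, the ratios of the lines had a Pearson r of 0.307 (simulated mean 0.219) and a Spearman rho of 0.239 (simulated mean 0.208). The ratios had the same sign in 57.5% of kept probe sets, within the simulated range of 54.9% to 58.4%. The covariance of the ratios was 0.115 against a simulated 0.081, a difference of 0.034. With a control share of 70% the simulated covariance averaged 0.113, and 36 of 100 simulations reached the observed value. With 80% it averaged 0.129, and 95 of 100 did. The share given to the control sets the simulated covariance by construction. The simulated noise was also drawn from line 13 ratios, which hold any effect of WIN1. Some share above 50% thus reaches the observed covariance with or without such an effect. These simulations therefore cannot tell what part of the excess is noise of the control.

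**Figure D2:**
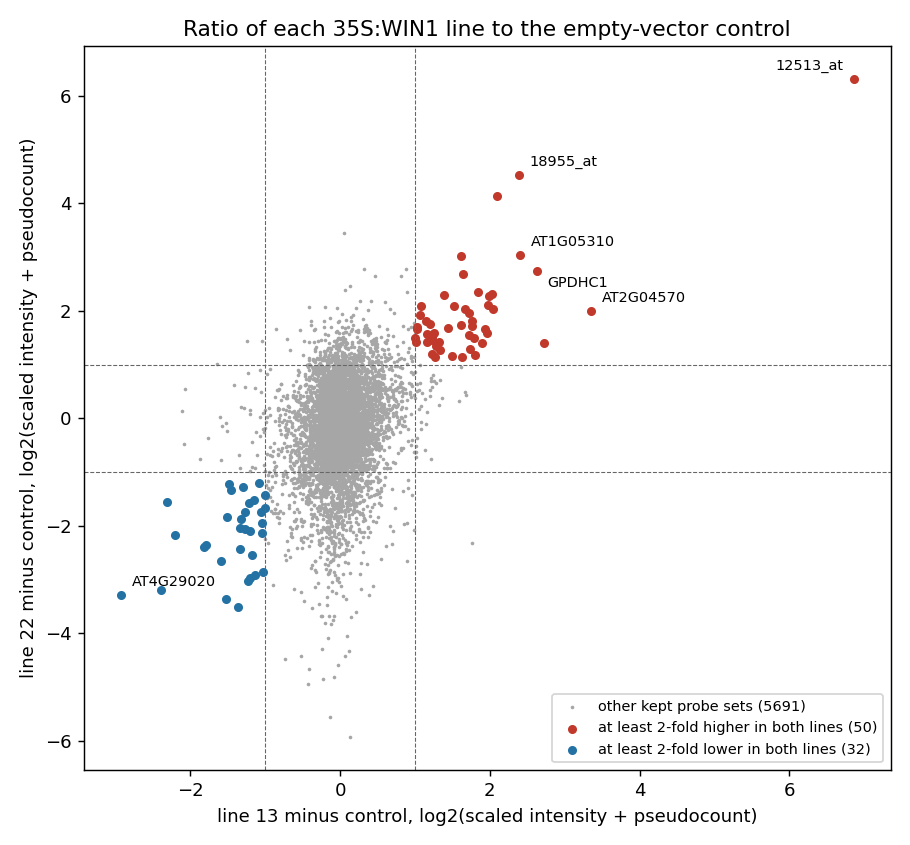
Log2 ratio to the control in line 13 (x axis) and in line 22 (y axis), on the log2(scaled intensity + pseudocount) scale, 1 point per kept probe set, with 1 array per line. The 50 probe sets at least 2-fold higher and the 32 at least 2-fold lower in both lines are coloured, 12513_at lies farthest out at 6.86 and 6.31, and the cloud is wider along the line 22 axis (SD 0.936) than along the line 13 axis (SD 0.401).

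Most of the listed wax and cutin genes were not matched to a probe set through the tables used here, in which many probe sets are unnamed. Of the 23 members of the list of wax and very-long-chain fatty acid genes, 1 matched a probe set: CER26 (AT4G13840), which acts in very-long-chain fatty acid elongation. It had scaled intensities of 257.7 in line 13 and 93 in line 22 against 403.4 in the control, log2 ratios of -0.61 and -1.92. No member was matched in the same way in the lists of cutin and suberin synthesis, lipid transfer proteins, epidermal, trichome and stomatal identity, salicylate-linked defence, auxin response, markers of flower, seed and root, and reference genes. In the list of plastid fatty acid synthesis, KAR (AT1G24360), the ketoacyl-ACP reductase, had log2 ratios of 0.11 and 0.73, the acyl-ACP thioesterase FATB had 0.42 and -0.66, and FATA was too dim to be kept. Of the cell wall list, the expansin genes EXPA4 (-0.10 and -0.98) and EXPA8 (-0.14 and -0.12) were measured and XTH33 was dim.

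Photosynthesis and cold-response genes formed the only lists with at least 3 measured members, and no member of any list passed limma, either over all probe sets or adjusted over the list alone (0 members each). The 5 photosynthesis genes LHCB4.1, PSAE1, RCA, PRK and SBPASE had a mean log2 ratio of -0.01 in line 13 and 0.58 in line 22, 0.29 over both lines, at the 89.6th percentile of random lists. Camera gave p = 0.0851 and adjusted p = 0.17 (adjusted p = 0.963 with an estimated correlation). On the deposited values without scaling this mean turned to -0.28, after quantile normalization it was 0.08 and with common-median scaling 0.47, and in line 22 the brightest 20% of all kept probe sets had a median log2 ratio of 0.29. The 4 cold and abscisic acid genes COR15B, COR47, KIN2 and LTI30 had a mean of 0.42 in line 13 and -0.68 in line 22, -0.13 over both lines, at the 30.3rd percentile, and the probe sets of COR47 disagreed in line 22 (-1.29 and 0.66). Camera gave adjusted p = 0.908 (adjusted p = 0.963 with an estimated correlation), and the mean was 0.03 after scaling to a common median and -0.65 on the deposited values.

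The remaining lists had 1 or 2 matched members and were not tested. In the touch and wounding list the zinc finger gene ZAT10, also called STZ, had mean log2 ratios of 0.29 in line 13 and 0.74 in line 22, but its probe sets disagreed in line 22 (1.64 and -0.16), and WRKY53 had 1.08 and 0.23. The flavonoid gene DFR, a dihydroflavonol reductase, had 0.21 and 0.42, and WRKY6, of the senescence list, had 0.20 and 0.15. GI, a clock gene, had 0.34 and -0.53 as means of its 4 probe sets, which ranged from -2.62 to 1.12 in line 22. THI2.1 of the jasmonate and ethylene list and HSP17.6C and HSP22 of the heat shock list were too dim to be kept.

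The second comparison was between the transgenic lines, which differed from each other at least 2-fold in 1262 kept probe sets, 881 higher in line 13 and 381 higher in line 22. This count has no replicate check, because each line had 1 array. By single probe sets, those furthest above in line 13 read SAMDC (S-adenosylmethionine decarboxylase, a polyamine synthesis gene), AT5G44290, AT2G30600, AT1G75800 and AT4G19110, by 4.15 to 4.73 on the pseudocount scale. In line 22 the values for AT5G44290 (-29.4) and AT1G75800 (-3.7) lay below 0 and those for SAMDC (6.8) and AT4G19110 (9.5) under the pseudocount of 18.6, so the pseudocount sets the size and order of these differences. Those furthest above in line 22 read AT2G39430, AT2G45300, LCR67 (a plant defensin, also called PDF1.1), scpl26 and the actin gene ACT11, with a log2 ratio of line 13 to line 22 from -2.69 to -2.19. In line 13 the value for AT2G39430 (-7.9) lay below 0 and those for LCR67 (8.1) and ACT11 (7.8) under the pseudocount, so the same limit holds for these. The SAMDC probe set 16437_s_at had scaled intensities of 654.4 in line 13, 6.8 in line 22 and 692.5 in the control, whereas the SAMDC probe set 14721_s_at had 1263, 1119 and 1128. A second probe set also differed for AT2G30600, with 801.6 in line 13 and 919 in line 22, for AT2G45300, with 317.6 and 290.9, and for scpl26, with log2 ratios to the control of 0.10 and 0.64. These genes are therefore not shown to differ between the lines. Over kept probe sets, log2 intensity correlated with the control at r = 0.965 in line 13 and r = 0.84 in line 22. Among the 108 genes with several kept probe sets (228 in all), the SD of the log2 ratio within a gene was 0.216 in line 13 and 1.12 in line 22, a ratio of 5.20 (95% bootstrap interval 4.23 to 6.34).

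**Figure D3:**
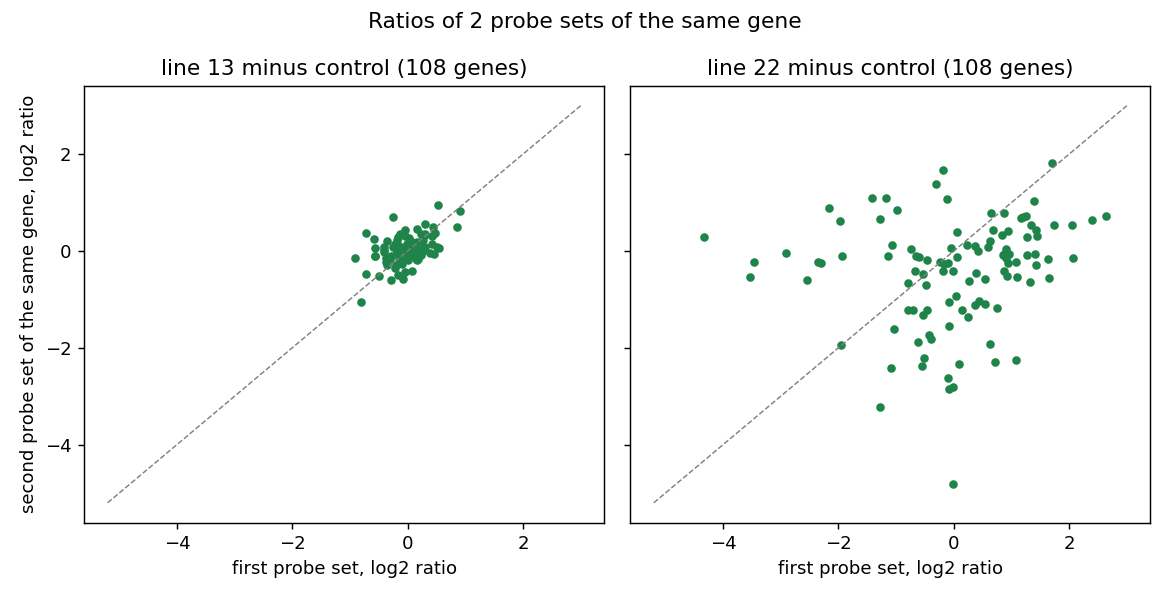
Log2 ratio to the control of the first (x axis) and second (y axis) kept probe set of each of 108 genes, on the log2(scaled intensity + pseudocount) scale, in line 13 and in line 22. Points on the dashed line have equal ratios, and the within-gene SD was 0.216 in line 13 and 1.12 in line 22.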

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

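All alternatives in this part were planned. No paired analysis was possible because the groups share fewer than 2 replicate numbers and there is 1 control. Leaving out either line leaves limma no residual degree of freedom, so its count has no value there. The 2 probe sets past adjusted p became 1 with common-median scaling, 0 with quantile normalization, 1 with a pseudocount at the 5th percentile, 4 with one at the 40th, 0 with a floor, 0 without the filter, and 1 with eBayes without trend and with robust eBayes. At a p under 0.05 without adjustment, quantile normalization gave 60, the floor 43 and no filter 307. The count was also 2 on the deposited values, where 1 of the 2 was shared, and with a filter at the 50th percentile, where both were.

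The 82 probe sets that were 2-fold apart in both lines (50 higher, 32 lower) became 129 (22, 107) on the deposited values, 147 (85, 62) and 39 (21, 18) with pseudocounts at the 5th and 40th percentiles, 146 with a floor (80 lower), and 47 (32, 15) with a filter at the 50th percentile. Without the filter 59 were lower. Fold thresholds of 1.5 and 3 gave 275 (132, 143) and 26 (20, 6). Each line alone gave 158 to 1372 (86 to 426 higher, 72 to 946 lower). Of the 82, 54 met the rule on the deposited values, 74 with common-median scaling and 78 after quantile normalization. The 1262 between the lines became 752 with a pseudocount at the 40th percentile, 2691 at 1.5-fold and 451 at 3-fold. The photosynthesis mean turned to -0.281 on the deposited values and ranged from -0.01 to 0.584 over the lines, and the cold-response mean turned to 0.029 with common-median scaling and ranged from -0.678 to 0.421. Filters and fold thresholds change counts by construction, and a larger pseudocount shrinks log2 ratios by construction. Leaving out the scaling lowered the ratios as a whole. The median over kept probe sets went from 0.006 to -0.27 in line 13 and from -0.09 to -0.78 in line 22. Other causes of these shifts were not tested. The correlation of the lines stayed between 0.299 and 0.347.

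For the 69 probe sets singled out by the rule or for their adjusted p there were 552 alternative values: 448 moved by no more than the SD between lines or kept their call, 93 moved by more, 10 lost a limma call (3 of 12513_at and 7 of 18955_at), 1 gained it (AT4G29020) and 0 changed sign among those called or 2-fold in both lines. The SD between lines was that of each probe set, from 0.002 for AT4G15140 to 3.34 for the SAMDC probe set 16437_s_at among those with a named gene. A small shift thus counted as a move for the first and a large one did not for the second, so these counts do not measure stability alike. Signal over background limits the dim genes: values at or below 0 have no order.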

Other observations

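The tests in this part were chosen after the results had been seen, except the 2-fold counts by choice of reference array and the noise simulation with a control as noisy as line 13. The bounds for the family means below were also set, in place of a p threshold, after those means were known. Families of genes beyond the fixed lists, 11 in all, were examined with 13 camera tests. Of the 15 measured GDSL-type lipase genes, AT2G04570 and AT2G42990 were at least 2-fold higher in both lines and 0 were lower by that rule, and the family mean was a log2 ratio of 0.22 (camera p = 0.0327, adjusted p = 0.212, and p = 0.263 with an estimated correlation). Of the 7 measured pectinesterase genes 1, AT1G05310, met the rule, and the mean was 0.47 (camera p = 0.00814, adjusted p = 0.106, and p = 0.224 with an estimated correlation). Leaving out the scaling moved all probe sets (median log2 ratios of -0.27 and -0.78 in lines 13 and 22): the GDSL mean was then -0.20 over 14 genes and the pectinesterase mean 0.09, and relative to the mean of the array medians they were 0.33 and 0.61 (0.26 and 0.51 with scaling). Without the genes that led to the choice, the mean over 13 GDSL genes was -0.119 (SE over members 0.137; 0.04 with common-median scaling and 0.01 after quantile normalization, each over 12 genes), and over 6 pectinesterase genes it was 0.091 (SE 0.119; -0.27 on the deposited values, 0.13 and 0.26 relative to the array medians). Both means plus 2 SE stayed under a log2 ratio of 1. The genes left had by selection not met the 2-fold rule, so this bound cannot decide on a shift of the whole family. The values show only that the 13 other GDSL genes and the 6 other pectinesterase genes were not 2-fold higher in both lines.

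Among the 8 reported families that share a symbol, 0 reached an adjusted p under 0.05 and 0 genes were 2-fold apart from the control in both lines. The aldehyde dehydrogenase genes had the lowest p of limma's camera test (mean log2 ratio 0.32 over 5 genes, or 0.36 relative to the array medians and 0.31 on the deposited values by that measure, where the plain mean was -0.21; adjusted p = 0.41, and p = 0.338 with an estimated correlation from camera in limma), led by ALDH6B2 at 0.90 in line 13 and 1.66 in line 22. The 11 UGT glycosyltransferase genes had a mean of -0.03 and included UGT71C2 at 0.68 and 1.14. The 5 WRKY transcription factor genes had a mean of 0.43 in line 13 and -0.45 in line 22. The means were -0.16 for 5 ATG, -0.28 for 5 GH, -0.15 for 5 NET, 0.14 for 5 scpl and -0.04 for 8 TBL genes. The GH group rests on the letters of the symbol alone and joins GH9 genes with GH3.9 (0.57), so its mean is not that of 1 family. The scpl mean joined -0.21 in line 13 and 0.48 in line 22. On the deposited values it was -0.32, and relative to the array medians it was 0.18 with scaling and 0.21 without. With common-median scaling the means of the ATG (0.001), TBL (0.10), UGT (0.12) and WRKY (0.14) genes lay above 0, the last 3 also after quantile normalization. Relative to the array medians those with common-median scaling were -0.105, -0.002, 0.015 and 0.032. In the UGT, WRKY and TBL families the mean was below 0 while camera placed the members above other genes (adjusted p = 0.889 for each).

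The ratios of line 22 to the control were wider than those of line 13. A difference between the arrays in the level or distribution of brightness is argued against as the whole cause. After quantile normalization the SD of the ratios in line 22 was still 2.26 times that in line 13 (2.33 before). Quantile normalization cannot remove noise that a dim array may carry. Such noise, where it fades with brightness, is argued against as the whole cause by the kept probe sets grouped by intensity. In the brightest group the SD of the ratios was 0.849 in line 22 and 0.35 in line 13. In the dimmest group it was 0.847 and 0.473, and line 22 had 0.931 to 1 in the groups between. The pseudocount shrinks the ratios of dim probe sets, so the dimmest values may be understated. Noise that does not fade with brightness was not tested. A gene-level expression difference of line 22 as the whole cause is argued against by probe sets of the same gene, whose intraclass correlation was 0.341 lower in line 22 (difference -0.341, 95% bootstrap interval -0.534 to -0.098). A candidate explanation is signal specific to single probe sets on the line 22 array, where the within-gene SD was 5.203 times that of line 13. That SD and the intraclass correlation come from the same split of the variance, so they are 1 observation. A gene-level difference as a part of the spread was not tested. Whether signal specific to single probe sets came from the RNA, the hybridisation or sequence differences of the line stays open, since line 22 had 1 array.

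With each array in turn as the reference of the other 2, the count of probe sets at least 2-fold apart was 82 with the control, 42 with line 13 and 985 with line 22, so 2 of the 3 choices gave as many, no share under 0.05 can be reached with 3 choices, and the separate position of the line 22 array shows in both this count and the limma counts (2, 0 and 2082, run after the data had been seen). The 82 lay above the 37 to 74 of the planned simulations, but that bound assumed a control as noisy as line 13, which 1 control array cannot check. With a control share of 60% of the variance 4 of 100 simulations reached 82, and with 70% 31 of 100 did. A larger share raises the simulated count by construction, and the noise was drawn from line 13 ratios that hold any effect of WIN1. The simulations therefore cannot decide whether noise accounts for the count. Noise of the control that is independent between probe sets is argued against as the whole source of the agreement of the lines. The covariance was taken between the line 13 ratio of 1 probe set and the line 22 ratio of another of the same gene. It was 0.068 (95% bootstrap interval 0.022 to 0.125) over 108 genes, and 0.042 (0.007 to 0.078) without the 2 genes that contribute most. Both intervals lay above 0. The covariance of the ratios over all kept probe sets, 0.115, lay within the first interval and above the second. Independent noise as a part of the agreement therefore stays open. Control noise shared by neighbouring probe sets of a gene stays open, since over the 51 genes whose probe set IDs lie more than 2 apart the covariance was 0.049 (-0.023 to 0.144), and 0.004 (-0.04 to 0.049) without the 2 genes that contribute most, intervals that include 0 and the corresponding values over all pairs (0.068 and 0.042). An effect of WIN1 shared by the lines and a difference particular to the control plants both stay open, as untested.

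Probe set 12513_at was the 1 kept probe set at or under the pseudocount in the control and over 16-fold higher in both lines on the pseudocount scale. Its limma adjusted p ranged from 6.1e-17 to 0.278 over the alternatives. A candidate explanation is that it reads the 35S:WIN1 transgene. The tables used here pair it with 0 loci, so this cannot be told apart from a response of another gene, and the missing pair is what keeps it open.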
